A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

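MYC ChIP-seq was analysed for P493 cells with shControl, shTerc and shTert hairpins and for primary Eµ-Myc lymphoma cells of Tert +/+ and Tert -/- mice on a C57BL/6 background. Per the labels, chromatin was fixed with formaldehyde, sonicated and precipitated with the c-Myc antibody N-262 of Santa Cruz, and single reads were sequenced on an Illumina instrument. Groups were taken from the treatment and title labels, with 1 library per group. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic, Bowtie2 2.2.3 and MACS2 2.0.10.20131216 were used, with the genome builds hg19 and mm10.

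Per the file headers, peaks were called per library and not on pooled samples, with MACS2, a fixed fragment length of 200 bp, reads of 35 bp, at most 3 tags per position, and local background windows of 1000 and 10000 bp. The cutoff in the headers was a p-value of 0.05 for 4 lists and a q-value of 0.05 for Tert -/-. Peak numbers in the peak names ran up to 651693 in shControl, 635644 in shTerc, 628689 in shTert, 199945 in Tert +/+ and 12567 in Tert -/-, so the deposited lists are a selection of the calls. No list held a peak with a −log10 q under 13 or a fold enrichment under 2, and the rule of the selection is not given in the sources used here. Per the file headers, the larger of the ChIP and input libraries was scaled to the smaller. The same P493 input served all 3 human lists, and each lymphoma had its own input.

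The deposited pileup at the summit is a signal in stacked tags, per the file headers. The deposited fold enrichment is a ratio of pileup to local background at the summit, as the authors' caller wrote it. The deposited p-values and q-values are on the −log10 scale. These are the authors' values, and they were used here to describe, rank or filter peaks within a list. Background at each summit was recomputed from pileup and fold, and a Poisson tail at that background gave the deposited −log10 p with a largest gap of 0.000252 over the peaks whose tail could be computed, which were 12831 of the 12852 in shControl.

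Peak lists were compared with bedtools 2.31.1, with an overlap of at least 1 bp counted as found. Chance overlap was the mean of 100 seeded shuffles within chromosomes. Control peaks were split into 10 bins of equal size by fold enrichment. Shares have Wilson 95% intervals from SciPy 1.17.1, which cover counting error only, and tags in ChIP libraries are not all independent molecules. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Depth was examined by thinning the summit pileup and background of each control peak to the tag number of the other library, with the lowest −log10 p of the other list as threshold, and again with that of the control list, so that depth alone changed. Only listed control peaks enter this step, and shTert, the deeper library, gave no thinning of shControl. The code of this step and of the overlap step was checked on simulated data built on the 12852 shControl peaks and, for thinning, also on the Tert +/+ peaks. Of planted overlaps 100% were found, and thinned numbers deviated from the drawn ones by at most 0.0408%. The draws used the same model as the thinning, so they do not test whether thinning mimics a shallower library.

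Alternatives were a stricter −log10 q of 20, merging of peaks within 1000 bp, an overlap of at least 50% of the peak, summits within 250 bp, lists of equal length, autosomes and X only, and strength by q or pileup. Alternatives added after the data were seen were 1 p threshold per system, thinning to the shallowest library of the system together with that threshold, the shares expected at the depth or p threshold of the other library, and the shTert list without its run on chromosome 3. Tables on gene annotation and genome sequence for hg19 and mm10 were not used here, so peaks are named by position, and gene names, promoters, gene lists, E-box motifs, genomic location and the comparison of human with mouse promoters, all planned, were not analysed here. The rule fixed beforehand names the 3 peaks with the highest fold enrichment of each list, and other peaks named were chosen after their values were seen. No p-value between conditions was computed, since each had 1 library.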

Results

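MYC binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in 2 systems in which a component of telomerase had been reduced or removed. TERT is the catalytic protein subunit of telomerase and Terc is its RNA template. The first system was P493, an established human B-cell line with a MYC gene that can be switched off by tetracycline, stably infected with a virus carrying a control short hairpin RNA (shControl), a hairpin against the telomerase RNA (shTerc) or a hairpin against TERT (shTert). The second was primary lymphoma cells of Eµ-Myc mice, whose Myc transgene is driven in B cells by an immunoglobulin enhancer, with either intact Tert (Tert +/+) or no Tert (Tert -/-). Each condition had 1 MYC ChIP library, so the series held 5 peak lists. The remaining 3 of the 8 samples were input DNA, of which 1 came from P493 and 2 from the lymphomas. No condition had a replicate, and no test between conditions was made. Wilson 95% intervals are given with shares of peaks and cover counting error only.

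The libraries differed in depth. After removal of excess duplicates, shControl held 32619600 tags, shTerc 22065142 and shTert 38824143. The Tert +/+ lymphoma held 22710775 tags and the Tert -/- lymphoma 9714712. The input of P493, used for all 3 of its lists, held 63069522 tags, and the inputs of the Tert +/+ and Tert -/- lymphomas held 30207336 and 27261867.

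**Figure D1:**
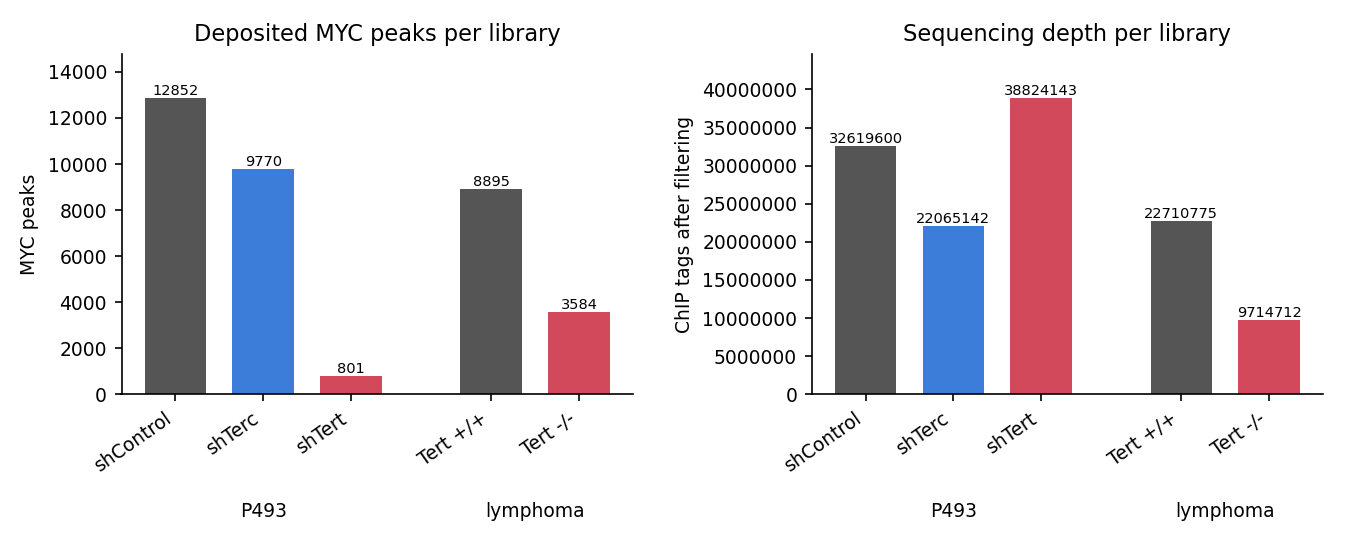
Bars give the number of deposited MYC peaks (left) and the number of ChIP tags after filtering (right) for the 3 P493 and the 2 lymphoma libraries, 1 library per bar. The shTert library had 801 peaks at 38824143 tags, against 12852 peaks at 32619600 tags in shControl.

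The comparison of shTert with shControl asks how MYC occupancy in P493 cells differed when TERT was targeted. The shControl list held 12852 MYC peaks and the shTert list 801, which is 6.23% of the shControl number, or 16.04-fold fewer. The shControl peaks covered 10.7 Mb and the shTert peaks 0.497 Mb. Of the shControl peaks, 744 overlapped a shTert peak, a share of 5.79% (5.40 to 6.21%), against a mean of 0.04995% when the shTert peaks were placed at random within chromosomes. In the other direction, 749 of the 801 shTert peaks, or 93.5% (91.6 to 95.02%), overlapped a shControl peak.

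Peaks not called in shTert included strong shControl peaks. Of the decile with the highest fold enrichment, 38.3% of 1286 peaks (35.7 to 41.0%) were found in shTert. The share was 10.3% in the next decile and 0.856% in the weakest. Peaks of shControl found in shTert had a median width of 1148 bp and a median fold enrichment of 18.3, while those not found had medians of 704 bp and 7.91. The 3 strongest shControl peaks, on chromosome 13 at 92000320 to 92002236 (69.0-fold over background), chromosome 7 at 45025382 to 45026684 (61.4-fold) and chromosome 12 at 56862070 to 56862600 (60.0-fold), each overlapped a shTert peak (positions in hg19). The strongest shControl peaks with no shTert peak were on chromosome 17 at 79678670 to 79679886 (38.7-fold), chromosome 2 at 206549714 to 206551260 (35.8-fold) and chromosome 6 at 43739001 to 43740347 (33.7-fold). These 3 were named after their values were seen, and each overlapped a shTerc peak. With both lists reduced to their 801 strongest peaks, 388 shControl peaks, or 48.4% (45.0 to 51.9%), were found in shTert.

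The shTert peaks were narrower, with a median width of 563 bp against 727 bp in shControl, and 8.99% of them spanned at least 1000 bp against 28.0%. Both lists passed a minimum that stood at a different p-value in each library. At the highest of the lowest deposited −log10 p values, the strictest, the shControl number was 14.6-fold that of shTert. The gap was wider at a −log10 q of at least 20, with 8271 shControl and 335 shTert peaks, and with both lists thinned to the shTerc depth and held to the common p-value, with an expected 7720 and 257. The run name in the header of the shControl list carried the name of a telomerase inhibitor, MST312, in place of the control hairpin. The run names of the other lists carried their own labels. The name of the tag file of the shControl list matched its label. The list is treated here as shControl, as labelled, in each comparison that uses it. Had its cells been given the inhibitor, these comparisons would lack a control without it.

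The comparison of shTerc with shControl asks the same of the telomerase RNA. The shTerc list held 9770 peaks, 76.0% of the shControl number, covering 8.19 Mb. Of the shControl peaks, 8062, or 62.7% (61.9 to 63.6%), overlapped a shTerc peak, against 0.705% for shuffled peaks. Of the shTerc peaks, 82.3% (81.5 to 83.0%) overlapped a shControl peak. The strongest decile of shControl by fold was found in shTerc to 99.4% (98.8 to 99.7%) and the weakest to 41.0% (38.4 to 43.7%). Ranked by q the weakest was found to 23.7%, and by pileup to 20%. Median widths were 747 bp in shTerc and 727 bp in shControl.

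The strongest shTerc peak lay on chromosome 13 at 91999156 to 92002037 (85.8-fold) and overlapped the strongest peak of shControl. It was followed by peaks on chromosome 19 at 1863925 to 1865162 (67.1-fold) and chromosome 17 at 42147790 to 42148795 (58.2-fold), and both overlapped peaks of shControl and of shTert. Of the shTerc peaks without a shControl peak, the strongest was on chromosome 11 at 5245973 to 5247760 (23.9-fold), named after its value was seen. The shTerc library had 22065142 tags against 32619600, and 42% of its reads were redundant against 31%. Thinned to the shTerc depth, shControl held an expected 8659 peaks, or 8573 when also held to the lowest −log10 p of the shTerc list. Against the 9770 of shTerc, these show no lower number beyond what depth gives. Only listed peaks were thinned, so any unlisted peak that would pass is left out. The thinning to that depth left 67.4% of shControl peaks, against the 62.7% found in shTerc. The shTerc hairpin was delivered in another vector than the control and TERT hairpins, so vector and target were not separated.

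**Figure D2:**
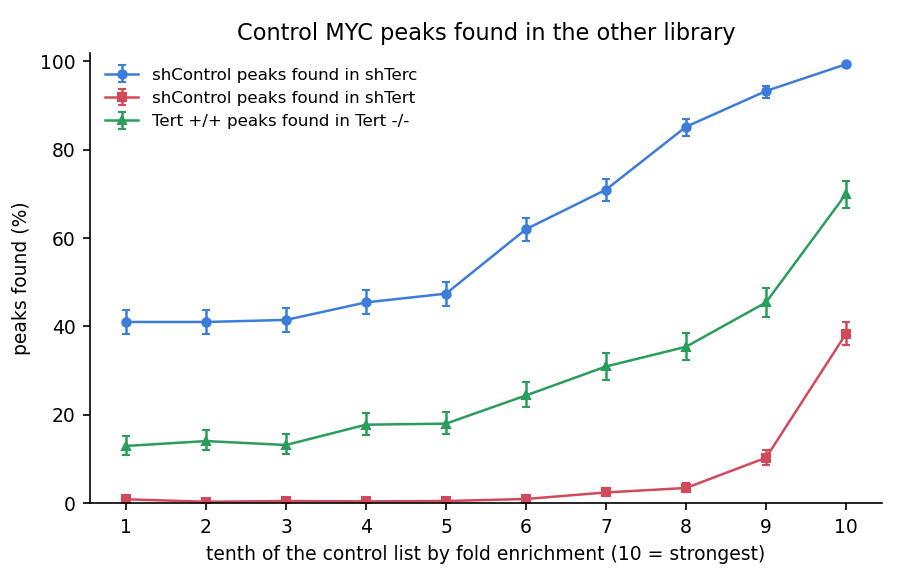
Each point is the percentage of control peaks overlapped by a peak of the other library, for deciles of the control list by fold enrichment, with Wilson 95% intervals as bars. In the strongest decile 99.4% of shControl peaks were found in shTerc and 38.3% in shTert, and 70.0% of Tert +/+ peaks were found in Tert -/-.

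The shControl peaks also called in shTert were nearly all called in shTerc as well. Of the 744 shControl peaks found in shTert, 733, or 98.5% (97.4 to 99.2%), were also found in shTerc, where 93.3% would be found if calls were independent among peaks of the same strength decile. A further 7329 shControl peaks, or 57.0% (56.2 to 57.9%), were found in shTerc and not in shTert, and 11 were found in shTert and not in shTerc. In neither knockdown library were 4779 peaks, or 37.2% (36.4 to 38.0%), found, against 36.9% for independent calls. That share could not exceed the 37.3% of shControl peaks absent from shTerc. Its excess is the same number of peaks as that among the 733, so it is not a separate result. The shTert and shTerc comparisons both use the single shControl library, so part of any excess may come from it. Part may also come from differences of strength left within a decile, as the strongest spanned 15.4- to 69.0-fold. Of the 801 shTert peaks, 738 overlapped peaks of both other lists and 47 overlapped neither.

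The comparison of the lymphomas asks how MYC occupancy differed in mouse tumours without Tert. The Tert +/+ lymphoma had 8895 MYC peaks covering 7.60 Mb and the Tert -/- lymphoma 3584 peaks covering 1.86 Mb, which is 40.3% of the number, or 2.48-fold fewer. Of the Tert +/+ peaks, 2509, or 28.2% (27.3 to 29.2%), overlapped a Tert -/- peak, against 0.203% for shuffled peaks. Of the Tert -/- peaks, 2573, or 71.8% (70.3 to 73.2%), overlapped a Tert +/+ peak. The Tert -/- peaks had a median width of 453.5 bp against 779 bp, and 4.10% of them spanned at least 1000 bp against 28.3%. The caller cutoff was a q-value of 0.05 for Tert -/- and a p-value of 0.05 for Tert +/+, so widths and covered lengths of these lists were set at unlike cutoffs. The Tert -/- library held 9714712 tags against 22710775. A Tert +/+ list thinned to the lower depth held an expected 3506 peaks, or 3340 when also held to the lowest −log10 p of Tert -/-. Against the 3584 of Tert -/-, these show no lower number beyond what depth gives. Only listed peaks were thinned, so any unlisted peak that would pass is left out, and a reversal is not shown. The same thinning left 39.4% of Tert +/+ peaks, or 37.6% with the threshold, against the 28.2% found in Tert -/-.

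Strong sites differed in both directions. In the strongest decile of Tert +/+ peaks, 70.0% (66.9 to 72.9%) were found in Tert -/-, and in the weakest 12.9%. The 3 strongest Tert +/+ peaks, on chromosome 1 at 86358007 to 86360772 (61.5-fold), chromosome 7 at 99467940 to 99469520 (60.1-fold) and chromosome 7 at 140137407 to 140138185 (57.8-fold), were each found in Tert -/- (positions in mm10). The 3 strongest Tert -/- peaks, on chromosome 3 at 53462844 to 53463993 (46.7-fold), chromosome 9 at 57520860 to 57521625 (45.3-fold) and chromosome 2 at 164441131 to 164441630 (45.0-fold), were each found in Tert +/+. Named after their values were seen, a Tert +/+ peak of 56.7-fold on chromosome 7 at 29000683 to 29002925 had no Tert -/- peak, and a Tert -/- peak of 36.6-fold on chromosome 5 at 113151404 to 113152003 had no Tert +/+ peak. Each genotype was represented by a single tumour library, so differences between tumours and between genotypes were not separated.

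The 3 strongest peaks of the shTert list did not overlap any peak of shControl or shTerc. They lay on chromosome 3 at 127815983 to 127816497 (30.8-fold), 127799945 to 127800532 (28.2-fold) and 127819270 to 127819749 (25.7-fold). They belonged to a run, noticed after the values were seen, of 10 shTert peaks within 38.5 kb, from 127799945 to 127838410 in hg19, in which neither other P493 list had a peak. The fold enrichment of these peaks ranged from 8.55 to 30.8 and their width from 382 to 588 bp. Among the 10 strongest shTert peaks, 5 belonged to the run. Without the run the shTert list held 791 peaks. Short DNA segments from outside the precipitation may give peaks like those of the run, so they are not shown to be MYC binding.

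**Figure D3:**
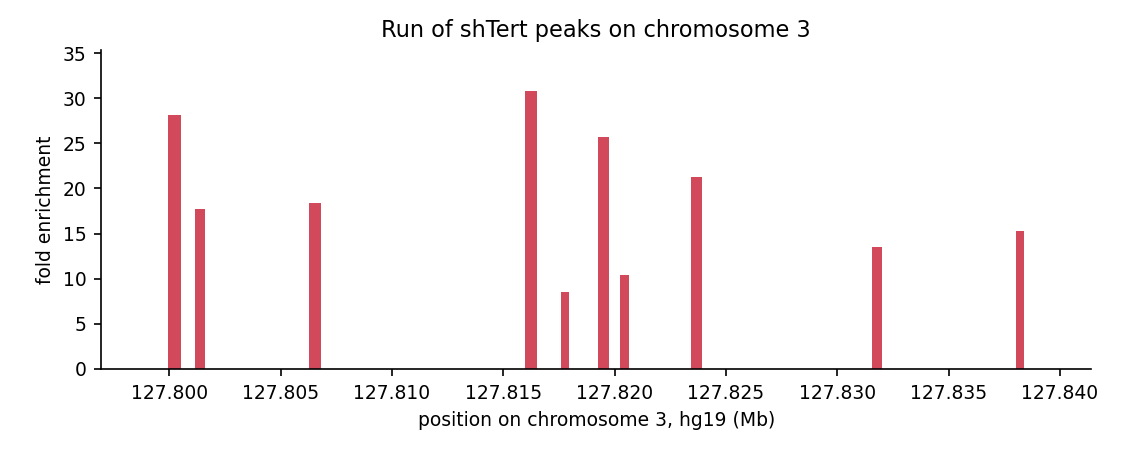
Bars mark the 10 shTert peaks of the run on chromosome 3, each drawn at its position in hg19 and to scale in width, with the fold enrichment over background as height. The peaks stood apart from each other, with gaps of 511 to 9166 bp.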

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

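Tests added after the data were seen are 1 p threshold per system, thinning to the shallowest library of the system together with that threshold, the expected shares at the depth or p threshold of the other library and the lists without the run on chromosome 3; the other alternatives were fixed before the data were examined. Over 15 results, 33 of 75 alternatives stayed within 1.5-fold of a peak number or within the Wilson interval of a share, and 42 did not. A stricter q left 8271 shControl, 6031 shTerc, 335 shTert, 5841 Tert +/+ and 1818 Tert -/- peaks, by construction fewer. Thinned to the shallowest library of each system (shTerc and Tert -/-) and held to its 1 p threshold, which are 2 choices together, 7720 shControl, 257 shTert and 3340 Tert +/+ peaks were expected, and shControl and Tert +/+ then lay below shTerc (8825, by the threshold alone) and Tert -/- (3584). The share of shControl peaks found in shTerc was 57.8% with overlap of at least 50% of the peak, 55.7% by summits, 79.3% with a stricter shControl list alone, 69.7% at equal length and 67.4% as predicted by the shTerc depth alone, or 66.7% with its p threshold as well. The reverse share was 78.5% by overlap of at least 50%, 73.3% by summits, 84.7% with a stricter q in both lists, 93.7% in shTerc alone and 70.3% at equal length. For shControl peaks found in shTert the values were 3.14% by overlap of at least 50%, 3.86% with a stricter q in both, 8.79% with a stricter shControl list alone and 48.4% at equal length, against 90.7% expected at the shTert p threshold, with no change of depth since shTert is deeper. The share of shTert peaks found in shControl was 87.9% by summits, 95.8% with a stricter shTert list alone and 48.9% at equal length. Tert +/+ peaks were found in Tert -/- to 17.4% by overlap of at least 50%, 26.3% by summits, 22.3% with a stricter q in both, 37.5% in Tert +/+ alone and 45.3% at equal length, against 39.4% expected at the Tert -/- depth alone and 37.6% with its p threshold as well. In reverse the values were 65.2% by summits, 79.3% with a stricter Tert -/- list alone and 46.9% at equal length. The strongest decile of shControl was found in shTerc to 100% ranked by q and 99.9% by pileup, and that of Tert +/+ in Tert -/- to 74.9% and 73.8%. Shares of the weakest decile were not among the results counted above. That of shControl was found in shTerc to 41.0% by fold, 23.7% by q and 20% by pileup. In shTert it was found to 0.856%, 0.467% and 0.311%. Of the shControl peaks, 44.1% were in neither knockdown library by summits. Beyond the number of peaks entering a list, the cause was not tested. With a stricter q, merged peaks, autosomes and X only, 1 p threshold or thinning with that threshold, the shTert list stayed below shControl in peak number. Alternatives on promoter windows, gene lists, E-boxes, genomic location and human against mouse promoters were not run. The Tert -/- library held 9714712 tags and shTerc 22065142, and depth limits what the lists thinned to them can show. No paired analysis was possible because each group has 1 library.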

Other observations

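Tests chosen only after the result was seen are those of depth for the shTert peak number, of strong peaks missing in either lymphoma, of depth with the threshold of the control list kept, of copy gain and peak width on the chromosome 3 run, and the use of intervals in reading the limits of 10 percentage points and 10 peaks.

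Fewer MYC peaks in shTert than in shControl were not a matter of depth, since shTert had 1.19 times the tags, nor of the p-value behind the q threshold, since shControl kept 14.6 times the peaks at 1 p threshold, nor of loss of the weakest peaks alone, since 38.3% of the strongest decile was found. A model cut the excess over background of every shControl peak by 1 factor, to 24.0%. It gave 50.2% for that decile, 11.9 percentage points from the share found and past the limit of 10 set beforehand. For shTerc the model, with a factor of 95.8%, was off by 0.613 points in the strongest decile and by 17.7 in the weakest. It expected 99.99% of the strongest decile in shTerc, near the ceiling, so that small gap is no contrast to shTert. The shTerc shares lay above the model in deciles 1 to 4 and below it in deciles 5 to 10. They were 71.0% against 83.1% in decile 7 and 85.2% against 93.9% in decile 8. In deciles 9, 8 and 7 of shControl the shTert share lay above the model, at 10.3% against 6.50%, 3.42% against 0.9002% and 2.41% against 0.186%, each beyond its Wilson interval. Deciles 1 to 6 lay above it as well, at 0.311 to 0.934% against 9.19e-05 to 0.0313%, each also beyond its interval. The end of the interval of the strongest decile's share found in shTert (35.7 to 41.0%) lies 9.19 points from the model, inside the limit of 10. The model assumes a profile with no other variation between libraries, so an even loss of enrichment and a selective one cannot be told apart. The shTert deciles go against 1 factor as the model has it. The shTerc shares also lay above it in weak deciles and below it in the strongest, with no lower peak number beyond depth. The shTert departures therefore do not show a selective loss. Less MYC on chromatin and a lower yield of this precipitation may both give such a list, and with 1 library neither was tested.

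The lower peak numbers in shTerc and in Tert -/- lymphoma do not lie below what depth gives: thinning alone left 0.886 times the shTerc number from shControl and 0.978 times the Tert -/- number from Tert +/+, and 0.878 and 0.932 times with the p threshold of the other list as well. Depth alone does not give which peaks were present in deciles by fold. Deciles 1, 2 and 3 of shControl were found in shTerc to 41.0%, 41.0% and 41.5%. At that depth and threshold 20.5%, 26.8% and 36.7% would be. Deciles 6, 7 and 8 of shControl were found in shTerc to 62.0%, 71.0% and 85.2%, against 79.9%, 93.0% and 98.9%. Ranked by q, deciles 1, 2 and 3 of shControl were found in shTerc to 23.7%, 30.2% and 38.2%. By pileup the shares were 20%, 30.6% and 39.5%. Shares expected at that depth were not computed for q or pileup, so the excess in the weak deciles is shown for fold alone. Of the strongest decile of Tert +/+ peaks 30.0% (27.1 to 33.1%) were missing in Tert -/-. At that depth alone 0.462% would be missing, and 0.568% with its threshold. The weakest decile by fold was found to 12.9% against 1.59% with both. Ranked by q the weakest was found to 9.34% and by pileup to 6.86%. Of the strongest decile of Tert -/- peaks 48 of 359, or 13.4% (10.23 to 17.3%), had no peak in the deeper Tert +/+ library. Tert genotype, differences between single tumours and precipitation quality stay open and untested.

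The run of 10 shTert peaks on chromosome 3 covered 12.1% of its 38.5 kb, which argues against a gain of copies of the whole interval. Its peaks had a median width of 466.5 bp, and 1.12% of 10000 random draws of 10 from 134 shTert peaks of at least the same fold shared with shControl had a median as small. The 52 shTert peaks without a shControl peak, the run among them, had a median width of 388.5 bp, not matched for fold. Small width was therefore not particular to the run, and the draws do not separate it from other peaks absent in shControl. Short DNA segments from outside the precipitation, such as carried-over amplicon, plasmid or complementary DNA, may give peaks like those of the run. The draws replaced a first version of the width test, which set the run's median against the lower quartile of 481.75 bp. An earlier test of gained binding was dropped as void because the run was chosen by its absence elsewhere. The densest interval of that length in shControl or shTerc held 9 peaks against 10 in the run. The bound of 10 was the run's own number, so it was not independent of the data, and 9 lies under it but within counting error. The much shorter shTert list held at most 4 outside the run. Its longest other run of shTert-only peaks, with gaps of up to 20 kb, was 1 peak. MYC binding gained on shTert cannot be told apart from carried-over DNA.

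A hypothesis that position near the chromosome start affects which MYC peaks stay in shTert was tested on chromosomes other than the acrocentric ones. Of shControl peaks in the first 5 Mb, 6.93% (5.38 to 8.89%) were found in shTert, and 6.41% would be at their strength, so no effect of position was detectable there. For shTerc the share in the first 5 Mb was 67.9% (64.6 to 71.1%), above the 63.8% at their strength. Strength here was fold alone. Across shControl peaks, being found in shTerc followed q (Spearman correlation 0.552) and pileup (0.553) more closely than fold (0.434). The higher shTerc share is therefore not shown to be an effect of position.

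Some chromosomes departed from the share their peak strengths gave. Of Tert +/+ peaks on X, 10.6% (5.67 to 18.9%) were found in Tert -/-, against 31.7% at their strength, the single departure among 20 mouse chromosomes. In P493, 4 of 23 chromosomes departed for shControl peaks found in shTerc: 48.5% (41.6 to 55.4%) on X against 62.0%, 56.7% on chromosome 6 against 66.3%, 69.6% on chromosome 9 against 58.0% and 68.0% on chromosome 19 against 62.8%. For shTert 2 of 23 departed, with 8.34% (6.73 to 10.3%) on chromosome 2 against 6.02% and 9.84% (7.39 to 12.99%) on chromosome 8 against 5.51%. With 95% intervals about 1 departure per comparison arises by chance, a count that does not weigh the size of a departure. X was low in reverse too, on the same overlaps. Of Tert -/- peaks on X, 47.4% (27.3 to 68.3%) were found in Tert +/+, against 72.6%. Of shTerc peaks on X, 64.4% (56.5 to 71.7%) were found in shControl, against 81.7%. The share of shControl peaks on X found in shTert stayed within its interval, at 5.56% against 5.30%. Strength here is fold enrichment alone. For shTerc, chromosome 6 had the highest share expected at strength and chromosome 9 the lowest. Their departures ran opposite to it and cannot be told apart from a poor match of strength.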
